A study of Mus musculus with 2 samples.

How the data were processed

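Gene expression was measured on 2 Affymetrix arrays of mouse bone marrow cells, 1 array of macrophages and 1 of osteoclasts. Per the labels' protocols, marrow of mice aged 8 weeks was grown for 3 days with M-CSF (macrophage colony-stimulating factor) and the adherent cells were taken as progenitors common to both cell types. These were then cultured for 6 days, per the sample labels, with M-CSF alone or with M-CSF plus RANKL, the cytokine that drives osteoclast formation, and were lysed. Total RNA was purified with Qiagen reagents, and 1 µg was turned into biotinylated cRNA by the one-cycle Affymetrix protocol, per the labels' protocols. The labels give the strain as C57/Black6 for both samples and do not say whether they came from the same animals.

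The deposited table holds a linear intensity for each of 45101 probe sets in each array, with no negative value. The method that condensed probes into probe sets, its background correction and its scaling are not given in the sources used here, nor is a detection call. The lowest deposited intensity was 0.0395 and the highest 17009 in the macrophage array, against 0.0431 and 10519 in the osteoclast array. The medians over the probe sets other than controls were 27.0 and 22.8, and the means after trimming 2% at each end were 173 and 127, so the authors' values were not scaled to 1 common level. The log2 difference of the medians, osteoclast minus macrophage, was -0.24. This is smaller than the 0.5 set before the data were examined as the sign of an unnormalized table, so the main values are those deposited, on the log2 scale. The tests, gene lists and rules described here were fixed at that time too, except where a later choice is stated. Centring on the median was then fixed as an alternative. Giving gene differences relative to the median shift was chosen after the shift had been seen, and the main counts are given on both scales.

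The 64 control probe sets were left out of all gene comparisons. Of the others, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 had none, and only the first kind was used. The Entrez identifiers of 34741 of these were found in the mouse RefSeq gene table of assembly GRCm38.p6, used for names only, and no symbol differed from it. They stood for 18193 genes. Each gene was read from its probe set with the highest mean log2 signal over both arrays, a rule that does not look at the difference. Among the 671 genes of the fixed lists, 68 had no probe set with a single symbol and are not analysed here. The genome build behind the array's annotation is not given in the sources used here, so no coordinates are printed. The annotation can be old.

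A floor marked the level under which a signal was not counted as measured. It was to be the 95th percentile of olfactory and vomeronasal receptor probe sets, genes not known to be used by these cells. With 78 such probe sets, fewer than the 100 required, the 40th percentile of all probe sets was used as laid down, which was 17.0 in the macrophage array and 14.4 in the osteoclast array. At this floor 20.5% and 15.4% of the receptor probe sets counted as measured, so genes just above it include background. A value below the floor was raised to it, so the difference of a gene measured in only 1 array is a lower bound. Folds written "at least" take the dimmer signal at the 95th percentile of the receptors, 28.3 and 25.8, a more cautious level chosen for them after the data were seen. Counts and list medians use the floor.

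With 1 array per group there is no replicate check, no test was possible, and no p-value is given. Genes were counted by size, at 2-fold (1 on the log2 scale) and 4-fold (2 on the log2 scale). The only error in the data is the spread between probe sets of the same gene. Its SD was 0.49 on the log2 scale, over 14641 probe sets of 5435 genes measured in both arrays. It covers probe-level noise and differences between transcript forms, and leaves out variation between cultures and animals. The number of arrays limits the precision of every value. For each of 24 gene lists and 10 lists of markers of other cell types, the median log2 difference of the measured members was compared with 10000 random lists of the same size, drawn from 20 bins of mean signal. The percentile describes these 2 arrays and is not a test.

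The genes named are 13 chosen beforehand, of which Acp5, Ctsk, Mmp9, Calcr, Nfatc1, Dcstamp, Atp6v0d2, Itgb3, Tnfrsf11a, Csf1r, Adgre1 and Irf8 are reported and 1 had no probe set with a single symbol and is not analysed here, the 10 largest differences in each direction among genes measured in both arrays, and, in each direction, the 5 brightest genes measured in only 1 array. From each list up to 3 members in each direction with the largest deposited differences of at least 2-fold were added, or up to 2 of the brightest where no member differed by 2-fold. Probe sets of unnamed transcripts and gene models were passed over. Uty, Kdm5d, Nnt, S100a8, S100a9, Cfb, Cxcl10, Tnfaip3, Lif, Ccnb2 and Cenpa fall outside this rule and were chosen after their values were seen. The 8 further granulocyte genes named at the end also fall outside this rule.

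The counting and the list percentiles were tested on simulated arrays made from the levels of the 18193 genes with this shift and this spread. Genes given a difference were drawn only from those measured in both arrays with a geometric mean signal over 100, so recovery near the floor was not tested. Of 50 such genes given a log2 difference of 1.5, 88.0% were found at 2-fold, and 86.0% of 50 given -1.5. All of those given 3 or -3 were found. Noise alone put 480 unchanged genes (3.75%) past 2-fold and 0 past 4-fold. The simulated noise had the same SD at every signal level, so these counts largely follow from that setting. They do not give the rate of false differences near the floor. A 25-gene list raised by 0.5 lay at percentile 99.9, and 95 of 100 unshifted lists lay inside the central 95%. Those unshifted lists were random draws from the simulated genes, so the second number was largely fixed by construction. It does not test lists of genes chosen by function. The error in the simulation was the probe set spread alone, so real noise between cultures is not covered. Alternatives were centring on the median, quantile and loess normalization, a higher floor, no floor together with no filter on measured genes, a pseudocount of 32, other rules for the probe set of a gene and 10 bins for the random lists. Scaling to hybridisation controls or to trimmed means and a floor at the 95th percentile of the receptors were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.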

Results

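Macrophages and osteoclasts, grown from marrow progenitors of a kind common to both per the labels' protocols, were each profiled on 1 array. The comparison asks which genes differ in expression between cells kept in M-CSF alone and cells given M-CSF plus RANKL for 6 days. Values of Xist, an RNA of female cells, and of Y-linked genes, given below, argue against animals of the same sex for both arrays. Differences between the treatments are therefore not separated from differences between the animals. Of 18193 genes with a probe set of their own, 11469 were above the floor in both arrays, 1192 in the macrophage array only, 986 in the osteoclast array only and 4546 in neither. Log2 signals of the genes measured in both arrays correlated across genes with Pearson's r = 0.927; genes are not independent replicates. Neither group has a replicate, so differences are compared with the spread between probe sets of a gene (SD 0.49 on the log2 scale), which contains no culture or animal variation.

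The osteoclast array was dimmer as a whole: the median log2 difference of the 23708 probe sets measured in both arrays was -0.43, a 1.35-fold lower signal. Differences below are given relative to this shift, as log2 of osteoclast over macrophage. The difference of the deposited values is 0.43 lower in every case, except where a bound was limited to 0. Signals are the deposited intensities. Folds written "at least" take the dimmer signal at the 95th percentile of the receptor probe sets (28.3 in macrophages, 25.8 in osteoclasts), while counts and medians use the lower floor. Relative to the shift, 970 genes were at least 2-fold higher and 954 at least 2-fold lower in the osteoclast array among the 13647 genes measured in at least 1 array, and 183 and 126 were at least 4-fold higher and lower. As deposited, 409 were 2-fold higher and 2390 were 2-fold lower, and 108 and 291 passed 4-fold. The higher genes thus made up 50.4% of the 2-fold genes relative to the shift and 14.6% as deposited.

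Among genes measured in both arrays, the 4 largest differences towards osteoclasts were in genes of bone resorption. Mmp9, a gelatinase, gave a signal of 30.4 in macrophages and 8767 in osteoclasts (8.61). Car2, carbonic anhydrase 2, gave 23.7 and 2415 (7.10), Acp5, the tartrate-resistant acid phosphatase, 104 and 8167 (6.72), and Ctsk, the collagen-degrading cathepsin K, 134 and 9202 (6.53). The other 6 of the 10 largest among genes measured in both arrays were Akr1c18, a hydroxysteroid dehydrogenase (6.37), the cytochrome P450 gene Cyp2s1 (5.68), Ocstamp, needed for osteoclast fusion (5.58), the surface glycoprotein gene Cd200 (5.50), Kbtbd11 (5.22) and the ketone body enzyme gene Bdh1 (5.18). Among genes below the floor in macrophages, the brightest in osteoclasts were the metallothionein gene Mt3, with a signal of 3351 (at least 160-fold higher), Akap6 with 526 (at least 25.1-fold), the sphingosine-1-phosphate transporter gene Spns2 with 324 (at least 15.5-fold), the Y-linked gene Eif2s3y with 321 (at least 15.3-fold) and the receptor kinase gene Mst1r with 283 (at least 13.5-fold). A second measured probe set of Akap6 gave 0.96.

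Towards macrophages, the largest differences among genes measured in both arrays were in Fcrls, an Fc receptor-like scavenger receptor, with 2305 against 16.6 (-6.68), and in Xist, the RNA that silences one X chromosome in female cells, with 1872 against 22.1 (-5.97). Cd5l, which encodes a protein secreted by macrophages, followed with 4792 against 81.6 (-5.44), then Ctla2b (-4.72), Nanos1 (-3.91), Hpgd, a prostaglandin-degrading enzyme (-3.83), the ribonuclease gene Ang (-3.49), Xylt2 (-3.36), the proton-sensing receptor gene Gpr65 (-3.29) and Sh3bp5 (-3.26). Tspan33 (278 in macrophages), Ctnnd2 (190), Pcp4l1 (172), the histone deacetylase gene Hdac9 (161) and Rasgrp3 (134) were the brightest genes measured in the macrophage array only. These 5 were at least 7.98, 5.44, 4.93, 4.61 and 3.83 times as high there. The Y-linked genes Uty and Kdm5d, chosen after their values were seen, had signals of 14.7 and 6.14 in macrophages, below the floor, and of 72.7 and 63.5 in osteoclasts. The Xist and Y-linked values stand beside every group described here, since they set the same 2 arrays apart.

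For 14 of the named genes measured in both arrays, the dimmer signal lay under this 95th percentile, in the range of background, so that their values are close to bounds and their order is not settled. Raised to that level, Fcrls was at least 66.1-fold, Xist at least 53.7-fold and Nanos1 at least 12.8-fold lower in osteoclasts, and Car2 was at least 115-fold, Akr1c18 at least 62.9-fold, Cyp2s1 at least 48.1-fold, Kbtbd11 at least 32.9-fold and Calcr at least 11.5-fold higher. The other 6 were Il10, Prtn3, Treml1, Epor, Cd79b and Cd8a. Of these, Cd79b was then under 2-fold, and Cd8a was under 2-fold relative to the shift before and after.

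**Figure D1:**
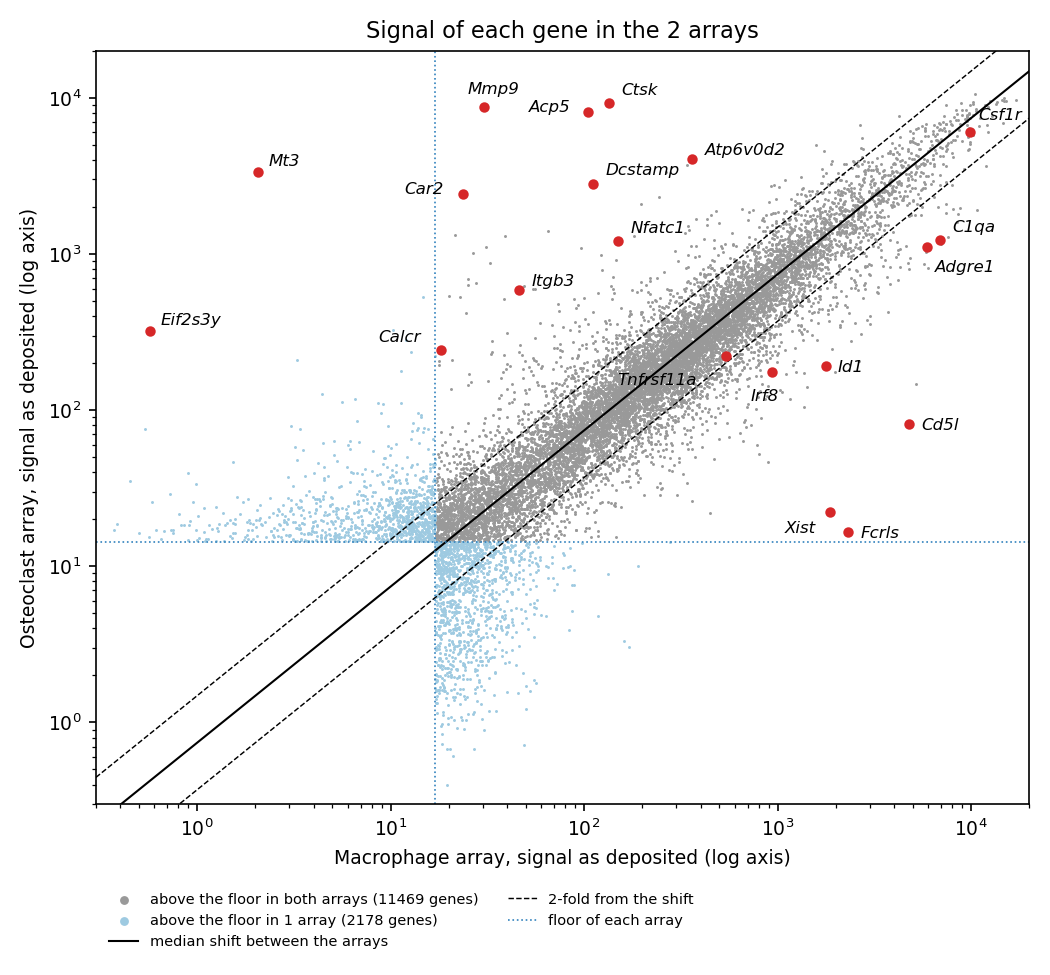
Deposited signal of each measured gene in the macrophage array (x axis, log scale) and the osteoclast array (y axis, log scale), 1 array each; the solid line is the median shift of -0.43, the dashed lines lie 2-fold from it and the dotted lines are the floors. Mmp9, Ctsk, Acp5 and Car2 lie far above the line, Fcrls, Xist and Cd5l far below it, and Csf1r close to it.

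As a group, the genes of osteoclast identity and resorption were higher in osteoclasts. Of 24 measured members, 19 were at least 2-fold higher relative to the shift (18 as deposited), none was 2-fold lower (1 as deposited) and the median was 2.56, above all of the 10000 matched random lists. Dcstamp, the fusion receptor, differed by 5.10, Calcr, the calcitonin receptor, by 4.16, Itgb3, the integrin chain of the osteoclast vitronectin receptor, by 4.11, and Nfatc1, the transcription factor of osteoclast differentiation, by 3.44. All 5 probe sets of Nfatc1 were higher, between 1.14 and 3.44. Tnfrsf11a, which encodes RANK itself, was not higher: its signal was 542 in macrophages and 223 in osteoclasts (-0.85), and its other probe set gave -0.32.

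Subunits of the vacuolar proton pump, which acidifies the resorption space, were higher by less. The median of 20 measured subunits was 0.74 (0.30 as deposited), above all of the random lists. Of these, 8 were at least 2-fold higher (3 as deposited) and 1 was 2-fold lower on both scales. Atp6v0d2 differed by 3.92 (363 against 4068), Atp6v1b2 by 1.45 and Tcirg1, the a3 subunit found in osteoclasts, by 1.45. Atp6v0a1 was lower (-1.43), with its probe sets from -1.66 to 0.38. Probe sets of Atp6v1b2 ranged from 0.20 to 1.45.

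Members of RANK signalling and osteoclast transcription factors had a median of 0.47 over 28 genes (0.036 as deposited), also above all of the random lists, with 8 at least 2-fold higher and 1 lower relative to the shift, against 6 and 4 as deposited. The coactivator gene Ppargc1b differed by 4.10 (49.0 against 625) and Jdp2, an AP-1 family member, by 4.09 (265 against 3347). Camk4, the 1 lower gene, was at least 1.20-fold lower, under 2-fold at the higher background level, and Fcer1g, the Fc receptor gamma chain, differed by -0.93. Known negative regulators of osteoclast formation lay on the other side. Their median was -1.06 over 13 genes, below all of the random lists, with 7 at least 2-fold lower (10 as deposited) and 2 higher (1 as deposited). Id1 differed by -2.77, Bcl6, a transcriptional repressor, by -2.07 and Irf8 by -1.97, with the other Irf8 probe set at -1.63. Socs3, an inhibitor of cytokine signalling, was higher (2.82), as was Tnfaip3 relative to the shift (1.08).

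Mitochondrial energy genes were higher in osteoclasts as a set. All 17 measured genes of the tricarboxylic acid cycle lay above the shift (16 were above 0 as deposited), with a median of 1.06 (0.63 as deposited) and 9 at least 2-fold higher relative to the shift but 0 as deposited. The citrate synthase gene Cs differed by 1.21 and Mdh2 by 0.81. Of 56 genes of oxidative phosphorylation, 55 lay above the shift and 48 above 0 as deposited. Their median was 0.79 (0.36 as deposited), and 18 were at least 2-fold higher relative to the shift but 1 as deposited, Uqcrfs1 of complex III (1.83, 1022 against 2701). Both medians were above all of the random lists. The list for mitochondrial biogenesis had a median of 0.46 over 13 genes, at percentile 99.5, with Ppargc1b far ahead of the rest. As deposited its median was 0.025. Glycolysis genes did not stand apart. The median of 17 genes was 0.17 (-0.26 as deposited) at percentile 87.0, and none was 2-fold higher. The hexokinase genes Hk3 and Hk2 differed by -1.71 and -0.94.

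**Figure D2:**
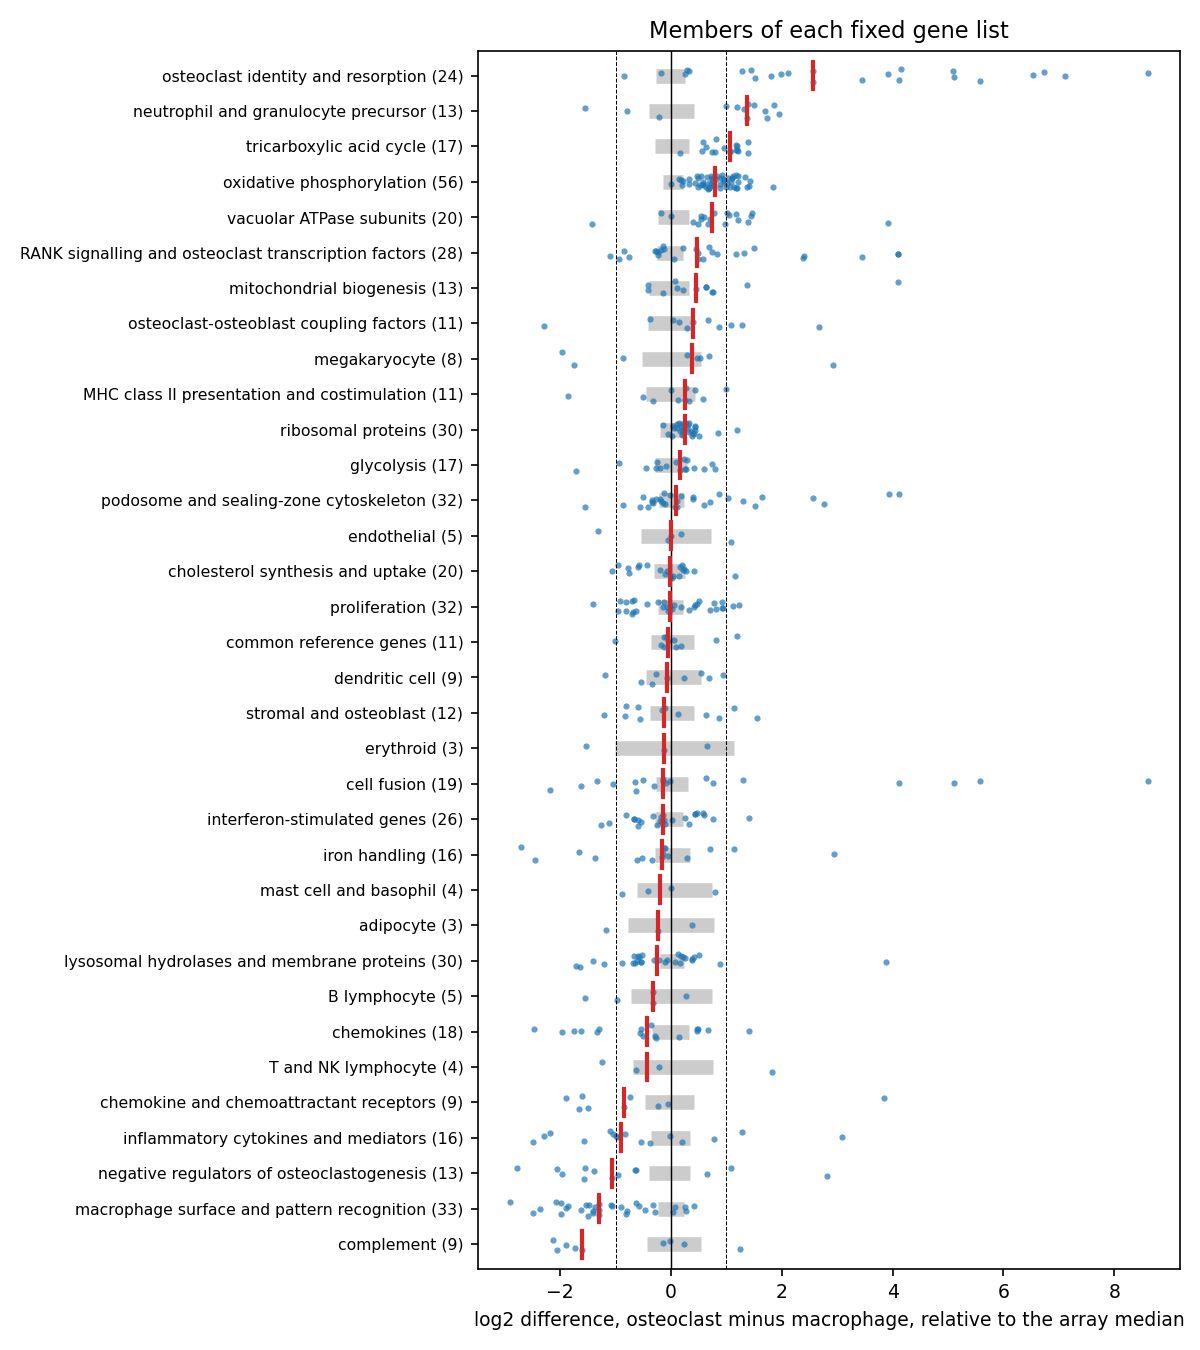
Log2 difference, osteoclast minus macrophage relative to the shift (x axis), of the measured members of each fixed gene list (blue points, number in parentheses), with the list's median (red bar) and the central 95% of medians of 10000 matched random lists (grey). The osteoclast list (median 2.56) and the complement list (median -1.62) lie at the 2 ends.

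Genes of the macrophage surface and of pattern recognition were lower in osteoclasts. Of 33 measured members, 20 were at least 2-fold lower relative to the shift (25 as deposited), none was 2-fold higher, and the median of -1.30 was below all of the random lists. The Fc receptor gene Fcgr1 differed by -2.91 (1425 against 141), Tlr13 by -2.50, Ly86 by -2.36 and Adgre1, which encodes the F4/80 antigen, by -1.99 (5919 against 1107). Csf1r, the M-CSF receptor, stayed near the shift (9899 against 6005, -0.29). Complement genes had a median of -1.62 over 9 genes, also below all of the random lists, with 5 at least 2-fold lower on both scales and 1, Cfb (1.25), higher relative to the shift (0 as deposited). C1qc differed by -2.13, C1qa by -2.06 and the C5a receptor gene C5ar1 by -1.89. C5ar1 is also a member of the macrophage surface list, and both C5ar1 and C3ar1 are members of the chemoattractant receptor list, so these lists are not independent. The same holds for the osteoclast and proton pump lists, which share Atp6v0d2, and for the chemokine and interferon lists, which share Cxcl10.

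Inflammatory mediators and chemotaxis genes had list medians below the shift, although most chemokines differed by less than 2-fold. The 16 measured cytokines and mediators had a median of -0.90, below all of the random lists, with 6 at least 2-fold lower and 2 higher, against 9 and 1 as deposited. Il10 differed by -2.49, Igf1 by -2.29 and Ptgs2, the inducible cyclooxygenase, by -2.18, with Ptgs2 probe sets from -2.18 to -0.76. Il1rn, the interleukin 1 receptor antagonist, was higher (3.08, 146 against 916), and Lif differed by 1.27, with another probe set at -0.17. As the list mixes members of unlike action, such as this antagonist, its median gives no direction of inflammatory activity. Among 18 chemokines the median was -0.43 at percentile 0.69. Of these 6 were at least 2-fold lower on both scales, with the largest differences in Ccl4 (-2.47), Pf4 (-1.97) and Ccl3 (-1.75), and 1 was higher relative to the shift, Cxcl10 (1.40). Chemoattractant receptors had a median of -0.84 over 9 genes at percentile 0.04, with 4 at least 2-fold lower (6 as deposited) and 1 higher. Ccr2 (-1.66) and C3ar1 (-1.62) were lower. Ccr1 was higher (3.85, 196 against 2095).

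Members of several lists went both ways, and the 95% binomial interval of the median, over the members, included 0 relative to the shift. It ran from -0.18 to 0.83 for RANK signalling, from -1.97 to 0.64 for negative regulators, from -0.15 to 0.75 for mitochondrial biogenesis, from -2.06 to 0.23 for complement, from -1.57 to 0.20 for inflammatory mediators, from -1.34 to 0.47 for chemokines, from -0.59 to 0.16 for lysosomal genes and from -0.22 to 1.74 for granulocyte genes.

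Several programmes did not stand apart from matched random lists by their median, which does not show members that moved both ways. Relative to the shift, 14.1% of all measured genes were at least 2-fold apart. Interferon-stimulated genes had a median of -0.15 over 26 genes (-0.59 as deposited) at percentile 17.8. Relative to the shift 2 were at least 2-fold lower, Bst2 (-1.26) and Ifit2 (-1.13), and 1 was higher, Cxcl10 (1.40), against 7 and 0 as deposited. Dhx58 differed by -0.81. Genes of MHC class II presentation had a median of 0.25 over 11 genes (-0.18 as deposited) at percentile 88.5, with H2-DMa at -1.85. Proliferation genes had a median of -0.024 over 32 genes (-0.46 as deposited) at percentile 44.8. Ccne1, Mcm3 and Mcm2, which act at the start of DNA replication, differed by -1.41, -0.96 and -0.93. Relative to the shift 2 members were at least 2-fold higher, Ccnb2 (1.23) and Cenpa (1.12), and 1 was lower, against 0 and 10 as deposited. Podosome and sealing-zone genes had a median of 0.091 over 32 genes (-0.34 as deposited) at percentile 79.6, and 8 were at least 2-fold higher (6 as deposited), led by Itgb3, Myo1d (3.94) and the exchange factor gene Dock5 (2.76). Probe sets of Myo1d ranged from 1.32 to 3.94. Ptk2b (-1.56) and Vav3 (-0.87) lay lower. The cell fusion list had a median of -0.15 over 19 genes at percentile 14.8, with 5 at least 2-fold higher and 4 lower, against 4 and 6 as deposited. It combined Mmp9, Ocstamp and Dcstamp with lower values of Trem2 (-2.18, other probe set 0.18), Adam8 (-1.62) and Cd81 (-1.34).

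Lysosomal genes had a median of -0.26 over 30 genes (-0.69 as deposited) at percentile 0.70. Scarb2 (-1.72), cathepsin H gene Ctsh (-1.64) and the acid lipase gene Lipa (-1.41) were lower, and Arsb was higher (3.88, 340 against 3701), with its probe sets from 0.79 to 3.88. Ribosomal protein genes had a median of 0.25 over 30 genes (-0.18 as deposited) at percentile 97.4; the brightest, Rpl38 and Rplp2, differed by 0.031 and 0.27 (-0.40 and -0.16 as deposited). Common reference genes had a median of -0.054 over 11 genes (-0.49 as deposited), with Hprt at -1.02. The ratio of 3' to 5' control signals, a measure of RNA integrity, was 0.748 in macrophages and 0.862 in osteoclasts for Gapdh, and 1.23 and 1.21 for beta-actin. For the 4 bacterial poly-A controls, which are labelled with the sample, it was higher in the osteoclast array, at 1.00 and 1.52 for lys, 2.45 and 3.11 for dap, 1.75 and 2.0 for phe, and 2.95 and 3.09 for thr.

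Markers of other cells that a marrow culture can hold were read in the same way. Granulocyte genes were higher in the osteoclast array. The median of 13 measured genes was 1.37 (0.94 as deposited), above all of the random lists, with 9 at least 2-fold higher and 1 lower relative to the shift, against 5 and 2 as deposited. The granule protein genes Prtn3 (22.2 against 63.5, 1.95) and Mpo (36.2 against 89.3, 1.74) and Elane (at least 2.18-fold higher) were dim, while Fcnb, the 1 lower gene, was at least 1.64-fold lower, under 2-fold at the higher background level, and Chil3 differed by -0.79. No other marker list lay outside the central 95% of random lists. Medians were -0.13 for stromal and osteoblast genes (12 measured, Tnfrsf11b -1.20, Sparc -0.84, Cxcl12 -0.81, Dcn at least 1.76-fold higher), -0.073 for dendritic cells (9, Batf3 -1.19) and 0.38 for megakaryocytes (8, Treml1 -1.75, Gp9 at least 1.01-fold lower, Vwf at least 4.55-fold higher). They were -0.33 for B lymphocytes (5, Cd79b -1.55, Pax5 at least 1.10-fold lower) and -0.43 for T and NK lymphocytes (4, Il7r -1.25, Cd8a -0.64, Cd5 at least 2.14-fold higher). For endothelial cells (5, Eng -1.32) the median was 0.00, for erythroid cells (3, Epor -1.53) -0.14, for mast cells and basophils (4, Mcpt8 -0.88) -0.20 and for adipocytes (3, Pparg -1.17) -0.24. Probe sets of Sparc ranged from -0.84 to 1.23.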

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

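This count was chosen after the data were seen. Probe sets that no comparison used also held a difference. Of 10092 probe sets with no gene symbol or with several, 5107 were above the floor in at least 1 array. Relative to the shift, 175 of them were at least 4-fold higher in the osteoclast array and 26 at least 4-fold lower, against 80 and 65 as deposited. They are not named here, and no explanation was tested.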

How the results depend on the processing

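Scaling to the hybridisation controls or to equal trimmed means, and a floor at the 95th percentile of the receptors, were chosen after the data were seen. The count of genes past a threshold depended on the scaling of the arrays, on the pseudocount and on the floor and filter. Against 409 genes 2-fold higher, 2390 lower, and 108 and 291 past 4-fold as deposited, centring on the median gave 970, 954, 183 and 126, quantile normalization 861, 1056, 184 and 134, loess 881, 1021, 181 and 132, scaling to the hybridisation controls 1192, 772, 206 and 103, and scaling to equal trimmed means 985, 940, 184 and 124. Without the floor and without the filter on measured genes, dropped together, the counts were 1789, 4359, 776 and 1482, and with a pseudocount of 32 they were 247, 1302, 61 and 142. The share of higher genes among the 2-fold genes ran from 44.9% to 60.7% over the 5 scalings. Of the genes 2-fold higher or lower after centring, 826 and 918 were so after quantile normalization, and 835 and 887 after loess. Among 680 genes at 2-fold with another measured probe set, 104 had a probe set of opposite sign.

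Centring and scaling to controls or trimmed means add 1 amount to every gene measured in both arrays, by construction. List medians that left the 95% binomial interval of the deposited median are given in the order centring, quantile, loess, hybridisation controls and trimmed means. They were 0.47, 0.50, 0.48, 0.57 and 0.48 for RANK signalling, 0.25, 0.15, 0.16, 0.35 and 0.26 for MHC class II, 0.79, 0.74, 0.72, 0.89 and 0.80 for oxidative phosphorylation, 1.06, 1.06, 1.04, 1.16 and 1.07 for the tricarboxylic acid cycle, and 0.46, 0.48, 0.53, 0.56 and 0.47 for mitochondrial biogenesis. They were 0.17, 0.13, 0.13, 0.27 and 0.18 for glycolysis, -0.022, 0.019, 0.045, 0.077 and -0.013 for cholesterol synthesis, 0.25, 0.19, 0.18, 0.35 and 0.26 for ribosomal proteins, and 1.37, 1.35, 1.39, 1.47 and 1.38 for granulocyte genes. Some lists left it under part of the scalings only: the proton pump (centring 0.74, hybridisation controls 0.84, trimmed means 0.75), lysosomal genes (-0.26, -0.16 and -0.25 in that order), macrophage genes (loess -1.22, controls -1.20), interferon-stimulated genes (loess -0.078, controls -0.053), proliferation (controls 0.076) and iron handling (controls -0.056, trimmed means -0.15). Without the floor and the filter together, which also admits unmeasured members, the mitochondrial biogenesis median turned to -0.10 and the adipocyte median to 1.29; the cause was not tested. Of the 34 lists, 30 had a value under every alternative. The erythroid, mast cell and adipocyte lists had none with the floor at the 95th or 99th percentile of the receptors, and the endothelial list none at the 99th. The side of the central 95% of random lists was kept, under the alternatives that gave a value, by 31 lists. Of the 12 alternatives, 3 apply 1 factor to every gene, which moves the percentile of a list only through members below the floor and so hardly tests it; over the other 9 the number was 31 as well, with 10 lists at percentile 0 or 100 as deposited. Coupling factors (percentiles 90.3 to 99.9), ribosomal proteins (96.6 to 98.6) and adipocyte markers (14.8 to 99.7) crossed it. Of the 121 named genes, 116 were at least 2-fold apart as deposited, and 0 of their 1276 values under alternatives had the opposite sign. Most were chosen for the size of their difference, and 1 factor for every gene moves a value by under 2-fold. With a floor a bound could not turn either, so this 0 was largely fixed in advance and says little on stability. Among the other 5 named genes, Rpl38 and Rplp2 turned from below to above 0, under 4 and 5 alternatives. Of 1330 values in all, 306 moved by more than the probe set spread. The probe set spread was 0.42 with the floor at the 99th percentile of the receptors and 0.52 without probe sets prone to cross-hybridise, against 0.49. Signal over background limits genes near the floor. No paired analysis was possible because each group has 1 array.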

Other observations

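Other gene groups differed member by member. In iron handling, the iron exporter gene Slc40a1 (3738 in macrophages against 425 in osteoclasts, -2.70 relative to the shift), the heme oxygenase gene Hmox1 (5984 against 812, -2.45) and Slc11a1, which encodes the phagosomal metal transporter (-1.67), were lower in osteoclasts, while the metalloreductase gene Steap4 was at least 4.60-fold higher. The list of 16 genes had a median of -0.16 at percentile 13.2. Among 11 factors by which osteoclasts are thought to act on osteoblasts, the sphingosine kinase gene Sphk1 was higher (2.66, other probe set 0.59) and Igf1 was lower (-2.29). The median was 0.39 at percentile 96.6. Cholesterol synthesis genes had a median of -0.022 over 20 genes at percentile 52.1, with Sc5d at -1.06, Hsd17b7 at -0.96 and Tm7sf2 at -0.78.

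Of the tests below, those on the X genes with a Y copy and on further granulocyte genes were set out before their results were seen, and the rest after. The first pattern is the dimmer osteoclast array. Bacterial hybridisation controls, added in a fixed amount, were lower by a median of 0.53 (SD 0.088, 9 of 9 probe sets lower; log2 difference -0.53), a larger drop than the shift of -0.43, so the controls point to no loss of signal in the genes beyond the scale of the arrays. The genes lay above the controls by slightly more than the SD of the controls, and whether scale is the whole of the shift stays open. A loss of signal limited to the brightest genes is argued against by a median of -0.46 in the genes outside the brightest of 4 equal bins of signal. The bacterial poly-A controls, which go through labelling with the sample, were lower still (median -1.56, 12 of 12 lower), 1.03 below the hybridisation controls (-1.03), more than unequal scaling predicts; less control RNA per sample mRNA is a candidate explanation that was not tested.

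The second pattern is the opposite behaviour of Xist and the Y-linked genes. All 3 Xist probe sets were at least 4-fold higher in the macrophage array with dim values taken as measured (1 gives -1.88 at the floor), which argues against noise of single probe sets, and all 3 Y-linked genes looked at were measured in the osteoclast array only. A response to RANKL in cells of a single animal is argued against by these 3 Y-linked genes beside Xist, since Y-linked transcripts need a Y chromosome, and exchanged labels are argued against by the osteoclast list (median 2.56). The Xist and Y-linked values also argue against animals of the same sex for both arrays. They go with animals of different sex, female for macrophages and male for osteoclasts. The 4 X genes with a Y copy add little to this. Their median was -0.25, with 3 of 4 lower in osteoclasts, at the edge of the error of 0.25 expected for a mean of 4 genes. Nnt, a mitochondrial gene partly deleted in the C57BL/6J substrain, was lower in 2 of 2 measured probe sets (-1.47 and -2.12) although oxidative phosphorylation genes were higher, so animals of different substrain may also be involved, but for Nnt this cannot be told apart from a response to RANKL with 1 array per treatment, and differences outside Xist and the Y-linked genes are likewise not separated from the animals.

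The third pattern is the higher granulocyte genes. Of the 13 measured, 10 were above the floor in both arrays and none is in another list; the abundant S100a9 (904 against 2161, 1.69) and S100a8 (1266 against 2133, 1.19) were higher and Chil3 was lower. The fixed list lay at percentile 100 of random lists matched on signal. This percentile also defined the pattern, so it is no separate test of a trend with signal level. After loess normalization, which removes such a trend, the median was 1.39 at percentile 100. More granulocytes among the osteoclast cultures would raise other granulocyte genes too. Of 8 such measured genes, 6 were higher, with a median of 0.47 at percentile 94.8, just under the 0.5 set as the prediction. Mgst1 (-1.63) and Padi4 (125 against 61.3, -0.59) were lower, and Ms4a3 (0.14) and Anxa1 (0.12) lay near the shift. The Padi4 value is opposite to what more granulocytes predict. The set tests more granulocytes weakly, since Anxa1 (9736 against 7828) and Mgst1 (4186 against 1000) were bright in macrophages. Cd177 (10.4 against 37.9) and Hp (16.5 against 52.0) were below the floor there and dim in osteoclasts. More granulocytes thus stay open as an explanation, as does a difference in expression within the cultured cells.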
